A study of Mus musculus with 13 samples.

How the data were processed

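Single-cell RNA sequencing was done on sorted epithelial cells from whole mouse colons. The labels give 13 libraries, of which 5 hold cDNA and 8 hold sample barcodes (MULTI libraries). Of the cDNA libraries, 3 are from antibiotic-treated mice and 2 from germ-free mice. Cells were pooled by condition before sorting, and proliferative (CD44-positive) and differentiated (CD44-negative) epithelial cells were taken in equal numbers, per the labels' protocols. The labels place all antibiotic libraries in one batch and all germ-free libraries in another. Control mice, which the series description mentions, were not analysed here, and neither were the barcode libraries.

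The authors deposited natural log values, 1 per gene and cell, for 32285 genes and 4183 cells. The scaling was read from the values themselves: the exponential of each deposited value minus 1 sums to 10000 in every cell. Dividing by the smallest nonzero value of a cell gave whole numbers, within 0.01, for 100% of the 9481333 nonzero values, so UMI counts (counts of unique molecules) were recovered and used. Cell Ranger 7.0.0, kallisto, bustools and the mm10 build are named in the submitters' processing notes, without their roles. The authors' filters on cells, and whether counting used strand, are not given in the sources used here.

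Cell names carry the condition and a number. Those of antibiotic cells (1, 2 and 3) equal the labels' library numbers, but those of germ-free cells (3 and 4) do not, so what the number stands for is open and cells were assigned to conditions and not to libraries. The 5 numbered parts are called cell sets here: antibiotic cell sets 1, 2 and 3, and germ-free cell sets 3 and 4. Since each condition was a single pool, no test was run and no p-value is given. The tests designed before the data were examined needed deposited counts per library. The design's rule for 1 pool per condition was used in their place.

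UMI counts were summed per condition and scaled by the condition's total UMI to CPM, with exact Poisson intervals. Ratios have conditional binomial intervals and shares of cells have exact Clopper-Pearson intervals, all at the 95% level. These intervals cover counting error only and say nothing about differences between mice. The log2 ratio is that of CPM + 1, germ-free over antibiotic, and it understates changes of low genes. A gene was ranked if it had at least 100 UMI in both conditions together and at least 20 CPM in the higher one. Its cell sets were called apart when both germ-free sets lay above, or both below, all 3 antibiotic sets, which random order gives for 20% of genes. The words higher and lower are used of genes whose cell sets were apart.

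Named genes are the 12 ranked genes with the largest log2 ratio in each direction whose cell sets were apart, plus up to 4 members with the highest CPM of each gene list. Ribosomal protein, mitochondrial, Xist and Y genes were left out of the ranking. This rule and the lists were fixed before the data were examined. The 2-fold limit for counts of genes, and the limits on detection and z-score in the naming of clusters, were set afterwards. Other genes named in the text were chosen after their values were seen: Oasl2, Ifit1, Ifit3, Pdk4, Car4, Ces2a, Tff3, Fcgbp, Reg1, Reg3g, Fabp1, Fabp6, Olfm4, Cd74 and Naprt. Some genes that the rule names are not reported here, though counts and medians of lists include them. A list member counts as measured with at least 100 UMI. Each list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean CPM, as a description of these pools. The interval of a list's median is the order-statistic interval over its members.

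Cells were clustered with Scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0, no batch integration). All deposited cells were kept. A cluster took the class with the highest mean marker z-score, provided that this was above 0, that at least 3 markers were found in at least 25% of its cells and above their level elsewhere, and that its 10 leading genes held no more markers of another class. A cluster with few UMI and no marker of its class among those genes stayed unnamed. Deep crypt secretory clusters were joined to the goblet class, a choice made after the data were examined. A stricter z-score limit of 0.5 was considered after the clusters were seen and is given only as an alternative. Scrublet, run per cell set, marked 23 cells (0.55%) as doublets, 17 of them germ-free. They were kept in the main analysis. Classes and clusters were compared between conditions where each condition had at least 20 cells.

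Gene positions are from GENCODE vM21 (mm10), matched by symbol for 31424 of the 32285 genes. The annotation release the authors used is not given in the sources used here. Other tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

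The contrast was tested on simulated data, with counts drawn for all 32285 genes from the antibiotic profile at the real cell set totals. Of the genes changed 2-fold in the germ-free sets, 100% had cell sets apart in the right direction, and of those changed 4-fold also 100%. Of 5943 unchanged genes, 34.9% had cell sets apart, with a median log2 ratio of -0.03, and 0% passed 2-fold. The simulated sets differed by counting error, and unchanged genes also by the slight shift that rescaling after the changes gave them. They lacked the further variation of real cell sets. The shares of unchanged genes may thus be too low for real data, and the 100% too high. Separation of cell sets alone is therefore weak evidence for a small change.

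Alternatives planned before the data were examined were stricter cells (at least 1000 UMI and at most 15% mitochondrial counts), thinning to 1000 UMI per cell, removal of doublets, median-of-ratios scaling, equal class shares, 10 CPM added, Leiden resolutions 0.5 and 2.0, and each cell set left out in turn. Those added later were means of per-cell values, totals without mitochondrial genes, removal of 2 clusters of almost only germ-free cells, removal of the unnamed low-UMI cluster, cells with a Y-gene UMI and no Xist UMI, removal of genes opposite a more abundant gene, the stricter z-score limit, and clustering without the genes that differed 2-fold (90 of the variable genes).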

Results

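The data describe sorted colon epithelial cells (EPCAM-positive and CD45-negative) of antibiotic-treated and germ-free mice, measured with a droplet 3' single-cell assay. The antibiotic pool held 3415 cells and 36530277 UMI, and the germ-free pool 768 cells and 3100880 UMI. Depth was unequal. Median UMI per cell were 6760, 6599 and 7420 in antibiotic cell sets 1, 2 and 3, against 1045 and 4682 in germ-free cell sets 3 and 4. Mitochondrial genes took 12.4% of antibiotic and 18.7% of germ-free UMI. Xist was at 209 CPM in antibiotic and 659 CPM in germ-free cells, and the Y gene Uty at 84.7 and 49.0 CPM, so the pools also differed in their balance of female and male cells. Gm42418, AY036118 and Lars2 together took 10.3% and 5.02% of UMI. Each condition was 1 pool in its own library batch, so condition and batch cannot be told apart in any comparison that follows, and there is no replicate error.

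The comparison of germ-free with antibiotic-treated epithelium asks how colon cells differ between mice raised without microbes and mice whose microbes were depleted. Germ-free cells had less RNA of most interferon-response genes measured, of 4 of 10 proximal colon genes and of several enzymes of lipid and drug metabolism. They had more RNA of some goblet cell products, such as Zg16 and Muc2, and of 6 of 10 distal colon genes. Within clusters, distal genes rose relative to proximal ones in 4 of 8 clusters with enough cells of both conditions. Of 6462 ranked genes, 111 were at least 2-fold higher and 118 at least 2-fold lower in germ-free cells with cell sets apart. At any size, 1902 of the ranked genes were higher and 1582 lower, and counts of list members are to be read against these. Cell sets were apart for 53.9% of ranked genes, where random order gives 20%. Simulated counts at the same totals, without the further variation of real cell sets, gave 34.9% of unchanged genes. Without germ-free cell set 4 the counts rose to 478 and 502. Only the 306 shallow cells of germ-free cell set 3 then had to lie outside the antibiotic sets, and 85.2% of ranked genes were apart. Without germ-free cell set 3 the counts were 110 and 111. With median-of-ratios scaling they were 88 and 156, which moves the share of higher genes from 48.5% to 36.1%. Other scalings moved it the other way, to 63.9% (242 and 137) with means of per-cell values and to 63.4% (175 and 101) with totals without mitochondrial genes. Without genes that lie opposite a more abundant gene, 63 genes were higher and 114 lower.

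The ranked genes lower in germ-free cells included a pair of interferon-response genes. Isg15, a ubiquitin-like protein induced by interferon (chromosome 4, 156199424 to 156200818), was at 45.8 CPM in antibiotic and 8.06 CPM in germ-free cells, 5.68-fold lower (3.84 to 8.81). Irf7, a transcription factor of the interferon response (chromosome 7, 141262706 to 141266481), was at 82.8 and 15.5 CPM, 5.35-fold lower. Gstp1 and Gstp2, glutathione transferases that lie next to each other on chromosome 19 and are close paralogs whose reads can be shared, were 7.93-fold and 7.18-fold lower. Cldn4, a tight junction protein, was 6.01-fold lower, and Il31ra, a cytokine receptor subunit, 6.51-fold lower. Il31ra was also among the 10 leading genes of the unnamed low-UMI cluster 12, along with Gm42418 and Lars2. It was at 418, 396 and 651 CPM in antibiotic cell sets 1, 2 and 3, and at 24.8 and 87.5 CPM in germ-free cell sets 3 and 4. In that order Gm42418, AY036118 and Lars2 together took 10.0%, 9.04%, 11.4%, 2.12% and 5.45% of UMI. A link between the shares and Il31ra was not tested. The others of the 12 were Gm11867, B930036N10Rik, Apol10b, Tsku, Gm19951 and Taco1, between 5.30-fold and 15.4-fold lower. The sizes depended on the germ-free cell set. Without germ-free cell set 4 the log2 ratio of Il31ra went from -2.69 to -4.33, that of Gstp1 from -2.89 to -4.85, of Isg15 from -2.37 to -3.75, of Gm19951 from -2.48 to -4.10, of Taco1 from -2.37 to -4.05 and of Apol10b from -2.56 to -3.39. It went from -2.45 to -1.64 for Cldn4, from -3.66 to -2.96 for Gm11867 and from -2.49 to -1.88 for Tsku. In germ-free cell set 3 Isg15, Gstp1 and Apol10b were at 2.48 CPM and Tsku at 4.96 CPM. There 3 counts correspond to 7.44 CPM, so sizes of these genes without set 4 lie at the floor of counting. With equal class shares Tsku was at -1.01 and Isg15 at -1.32, and after thinning Irf7 went from -2.35 to -1.73. Thinning also gave -1.47 for Isg15, -1.62 for Apol10b and -2.37 for Gm11867, while Taco1 went the other way to -3.15. Among cells with a Y-gene UMI and no Xist UMI the cell sets of Cldn4 were no longer apart.

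The list of antigen presentation and interferon genes had a median log2 ratio of -0.69 (-1.96 to -0.38) over 15 measured members, below all random lists, and of -0.31 with means of per-cell values. Of these members, 11 were lower, 1 was higher and 3 were not apart. H2-K1 and H2-D1, classical MHC class I genes, were at 366 and 310 CPM in antibiotic and 227 and 215 CPM in germ-free cells. Irf1 was at 65.7 and 38.7 CPM. B2m, at 344 and 263 CPM, was not apart. Oasl2 (4.99-fold lower), Ifit3 (6.13-fold) and Ifit1 (2.46-fold) lay in the same direction. Without germ-free cell set 4 their log2 ratios went from -2.18 to -3.45, from -1.96 to -3.16 and from -1.24 to -5.10, and with equal class shares that of Ifit1 was -0.54. In germ-free cell set 3 Oasl2 was at 2.48 CPM and Ifit3 and Ifit1 at 0 CPM. There 3 counts correspond to 7.44 CPM, so sizes without set 4 are set by the floor of counting. The member that was higher was Cd74, the invariant chain of MHC class II, at 2.52 and 13.9 CPM. Within colonocyte-like cells Isg15 was at 69.2 and 13.8 CPM and Irf7 at 126 and 23.8 CPM. An Isg15 UMI was found in 9.28% of antibiotic cells. The conditions shared colonocyte-like clusters 1, 4, 7 and 13, which held 22, 106, 38 and 31 germ-free cells. In that order Isg15 was at 5.95 and 0, 8.14 and 7.83, 167 and 0, and 51.9 and 36.3 CPM. Irf7 was at 59.5 and 28.8, 36.1 and 10.4, 185 and 27.8, and 78.8 and 27.2 CPM. Of colonocyte-like cells, cluster 1 held the most in the antibiotic pool. Cluster 2, with Isg15 at 19.8 CPM in germ-free cells, held the most in the germ-free pool.

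**Figure D1:**
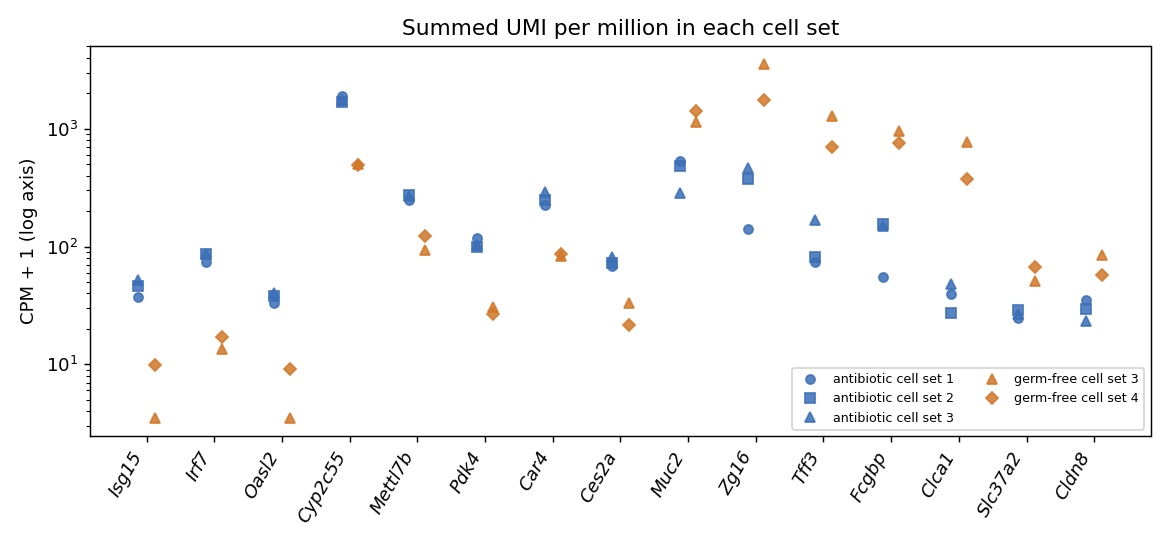
CPM + 1 on a log axis (vertical) of 15 genes (horizontal) in each of the 3 antibiotic and 2 germ-free cell sets, 1 point per cell set; several of these genes were chosen after their values were seen. Isg15, Irf7, Oasl2, Cyp2c55 and Pdk4 lie lower, and Zg16, Tff3, Fcgbp and Clca1 higher, in both germ-free sets than in all antibiotic sets.

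Several goblet cell products were higher in germ-free cells. Clca1, a secreted metalloprotease of mucus (chromosome 3, 145003817 to 145032776), was at 38.4 CPM in antibiotic and 425 CPM in germ-free cells, an 11.1-fold difference (10.3 to 11.9). Zg16, a lectin of the mucus layer, was at 365 and 2000.4 CPM, and Muc2, the main mucin of colon mucus, at 402 and 1390 CPM. Tff3 and Fcgbp were 6.66-fold and 6.00-fold higher. Without germ-free cell set 4 the log2 ratio of Clca1 went from 3.43 to 4.30, that of Zg16 from 2.45 to 3.29 and that of Tff3 from 2.72 to 3.45, and without antibiotic cell set 3 that of Tff3 was 3.32. With stricter cells Clca1 was at 4.12 and Muc2 went from 1.79 to 2.48, while equal class shares gave 0.91 for Muc2 and 1.84, from 2.58, for Fcgbp. The membrane mucins Muc3 and Muc13 were lower, at 1292 and 954 CPM and at 1594 and 1243 CPM. The list of mucus and goblet genes went both ways, with 6 of 15 members higher, 3 lower and 6 not apart, and a median log2 ratio of 0.12 (-0.36 to 2.45), which turned to -0.13 with equal class shares. Among goblet-like cells Clca1 was at 473 CPM in 255 antibiotic cells and 3661 CPM in 92 germ-free cells, Zg16 at 3896 and 16644 CPM, and Muc2 at 6428 and 12193 CPM. Most antibiotic goblet-like cells lay in cluster 10 and most germ-free ones in cluster 15.

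The other ranked genes higher in germ-free cells were led by Gip, the incretin hormone made by enteroendocrine cells (chromosome 11, 96024545 to 96030831). It had 4 UMI in antibiotic and 677 UMI in germ-free cells, or 0.11 and 218 CPM, a ratio of 1994 (775 to 7339). A Gip UMI was found in 51.2% of germ-free cells (median depth 2874 UMI), and in 61.8% of those in cluster 2 (median depth 3441 UMI), which is colonocyte-like and should lack the hormone, so the share is no measure of expression. Gip was seen in every cluster with at least 20 germ-free cells, the lowest at 97.4 CPM (cluster 7) and the highest at 463 CPM (cluster 12). Of the remaining genes, Pard3bos1, Gm15592, Tsix, Gm15563, Gm4876, Gm36975 and Gm20663 are annotated as antisense genes, whose reads cannot be told from those of their partners unless strand was used. They were between 8.09-fold and 29.6-fold higher. The partner of Gm20663, Gm4070, was at a mean of 2.34 CPM over the conditions, below Gm20663 at 7.25 and 58.7 CPM. Among the ranked lower genes, B930036N10Rik is also annotated as antisense. Lrp1b, Gm20528 and Insyn2a were 11.1-fold, 10.5-fold and 13.98-fold higher. With stricter cells the log2 ratio of Gm4876 went from 2.95 to 1.94, that of Gm15592 from 3.82 to 2.79, of Gm20528 from 3.34 to 2.64, of Insyn2a from 3.28 to 2.45 and of Gip from 7.63 to 6.84. Without germ-free cell set 4 that of Lrp1b went from 3.34 to 4.40, and among cells with a Y-gene UMI and no Xist UMI that of Tsix went from 3.38 to 1.23.

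The series title concerns regional identity of the colon, which the proximal and distal gene lists address. Of 10 measured proximal genes, 4 were lower in germ-free cells, none was higher and 6 were not apart, with a median log2 ratio of -0.26 (-1.16 to 0.42) at percentile 2.11 of random lists. The median was -0.84 without germ-free cell set 4 and -0.10 with cells thinned to 1000 UMI. Cyp2c55, a cytochrome P450 of the proximal colon, was at 1765 CPM in antibiotic and 492 CPM in germ-free cells, 3.59-fold lower (3.41 to 3.78). Mettl7b was at 264 and 118 CPM. Fabp2 (791 and 669 CPM) and Adh1 (246 and 202 CPM) were not apart. Of 10 measured distal genes, 6 were higher, 1 lower and 3 not apart, with a median of 0.47 (0.00 to 1.12) at percentile 99.9. Slc37a2 was at 26.0 and 63.5 CPM, Cldn8 at 26.8 and 59.7 CPM, and the posterior homeobox genes Hoxb13 at 80.5 and 103 CPM and Hoxd13 at 13.2 and 18.1 CPM. With equal class shares the log2 ratio of Hoxb13 turned from 0.35 to -0.22, and without germ-free cell set 4 that of Hoxd13 went from 0.42 to 1.23. Among cells with a Y-gene UMI and no Xist UMI that of Slc37a2 went from 1.26 to 0.45.

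Within clusters the shift was not uniform. The mean log2 CPM of distal genes minus that of proximal genes was higher in germ-free than in antibiotic cells in 4 of 8 clusters with enough cells of both. The mean difference over clusters was 0.36, with an SD over clusters of 1.19. The largest rise was in cluster 1, from -5.36 in antibiotic to -2.99 in 22 germ-free cells. There Slc37a2 and Hoxb13 were at 28.8 CPM in germ-free cells, the level of 1 UMI. In cluster 12, also among the 4, 3 counts correspond to 57.9 CPM in germ-free cells. Single counts thus weigh heavily in both clusters. In cluster 7, a colonocyte-like cluster with 38 germ-free cells, Cyp2c55 was at 1559 CPM in antibiotic and 1496 CPM in germ-free cells. In cluster 13, with 31 germ-free cells, it was at 2507 and 227 CPM. In cluster 4, the colonocyte-like cluster with the highest distal score, the difference between the lists was 1.62 in antibiotic and 1.02 in germ-free cells.

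**Figure D2:**
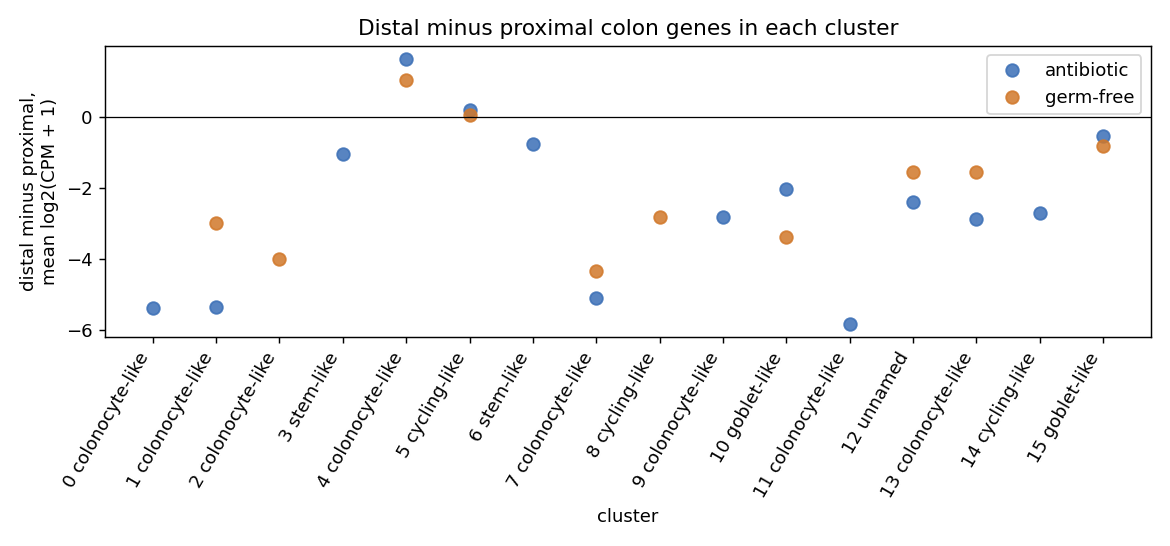
Mean log2(CPM + 1) of 10 distal minus that of 10 proximal colon genes (vertical) in each cluster (horizontal) for antibiotic and germ-free cells, 1 point per cluster and condition with at least 20 cells. Germ-free points lie above antibiotic points in 4 of the 8 clusters that have both.

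The title also names nicotinic acid. The list of nicotinic acid and NAD genes had a median log2 ratio of -0.06 (-0.23 to 0.21) over 16 measured members, at percentile 16.4 of random lists, with 4 higher, 4 lower and 8 not apart. With stricter cells (at least 1000 UMI and at most 15% mitochondrial) the median turned to 0.14. Slc5a8, a monocarboxylate transporter that also carries nicotinic acid, was at 126 and 207 CPM, and Cd38, an NAD-consuming enzyme, at 127 and 148 CPM. Nadk, the NAD kinase, was at 106 and 75.8 CPM, and Nampt at 67.1 and 57.1 CPM and not apart. Naprt, which starts NAD synthesis from nicotinic acid, was 1.38-fold lower (1.12 to 1.72). Without germ-free cell set 4 the log2 ratio of Slc5a8 went from 0.72 to 1.40, and after thinning that of Naprt went from -0.45 to -1.68.

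Genes of fatty acid oxidation and PPAR targets had a median log2 ratio of -0.16 (-0.53 to -0.02) at percentile 1.76, with 14 of 24 members lower, 4 higher and 6 not apart. Pparg was at 362 and 290 CPM and Hadha at 204 and 179 CPM, and with equal class shares the log2 ratio of Pparg turned from -0.32 to 0.23. Pdk4, a kinase that restrains pyruvate oxidation, was 3.95-fold lower (3.18 to 4.98). In the xenobiotic list, with 6 of 13 members lower and 1 higher and a median of -0.18 at percentile 2.90, the efflux pump Abcb1a was at 1091 and 543 CPM, Ces2c at 171 and 75.8 CPM and Cyp3a13 at 168 and 120 CPM, while Cyp2c65 (202 and 212 CPM) was not apart. Ces2a was 3.34-fold lower. Equal class shares moved the log2 ratio of Pdk4 from -1.94 to -0.53 and that of Ces2a from -1.70 to -0.80. Cholesterol synthesis genes had a median of -0.22 (-0.59 to 0.13) at percentile 0.46, with 9 of 17 lower and 1 higher. Srebf2 was at 144 and 124 CPM, while Hmgcs1 (147 and 177 CPM) was not apart.

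Ion and short-chain fatty acid transport genes went both ways, with 9 of 23 higher, 7 lower and a median of 0.00 at percentile 43.6. Car1, a carbonic anhydrase, was at 7370 and 3493 CPM, and Car4 was 3.10-fold lower (a log2 ratio of -1.62, and of -0.87 with equal class shares), while Car2 was at 609 and 881 CPM, Atp1b1 at 1054 and 1167 CPM and Nr3c2 at 1240 and 1349 CPM. Antimicrobial and defence genes had a median of 0.07 at percentile 67.7, which turned to -0.12 with stricter cells, with 5 of 18 higher and 5 lower. Pigr, the receptor that carries IgA, was at 1230 and 1917 CPM, Lypd8 at 3699 and 2643 CPM and Saa1 at 483 and 290 CPM. Reg3b (174 and 199 CPM) was not apart, while Reg3g was at 18.8 and 90.9 CPM and higher. With means of per-cell values the log2 ratio of Saa1 turned from -0.73 to 0.12. Injury and regeneration genes had a median of -0.30 (-1.12 to 0.48) at percentile 1.33, with 4 of 8 lower and 1 higher, and a median of 0.0021 with cells thinned to 1000 UMI. Plaur was at 100.3 and 45.5 CPM, Areg at 445 and 400 CPM and Itga2 at 60.5 and 84.8 CPM, and Anxa1 (123 and 105 CPM) was not apart. The log2 ratio of Areg, -0.15, turned to 0.030 after thinning, 0.067 with equal class shares and 0.15 with means of per-cell values.

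Proliferation genes had a median log2 ratio of 0.54 (0.20 to 0.90) at percentile 99.99, with 6 of 12 higher and none lower. Cenpf was at 23.5 and 51.0 CPM, a log2 ratio of 1.08 that was 0.022 without the clusters of almost only germ-free cells. Mki67 (59.3 and 80.6 CPM), Top2a (53.2 and 61.3 CPM) and Pcna (43.7 and 54.8 CPM) were not apart. With cells thinned to 1000 UMI the median was 0.11. Genes of the dissociation response had a median of -0.53 (-0.92 to -0.22), below all random lists, with 10 of 13 lower and none higher, a difference that moved with the condition. Jun was at 848 and 489 CPM, Jund at 617 and 264 CPM and Atf3 at 718 and 519 CPM, and Fos (648 and 583 CPM) was not apart. Of genes of other cell types, 4 were measured. Lyz1 was at 3.997 and 23.2 CPM and Sis at 32.4 and 43.2 CPM, while Cd52 (4.95 and 5.16 CPM) and Pecam1 (3.26 and 2.90 CPM) were not apart. Of 5 Xist and Y genes, Xist was higher and 4 Y genes were lower, Eif2s3y at 51.9 and 37.7 CPM and Ddx3y at 47.3 and 33.5 CPM. With equal class shares the log2 ratio of Ddx3y turned to 0.13, and among cells with a Y-gene UMI and no Xist UMI that of Sis turned to -0.17.

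**Figure D3:**
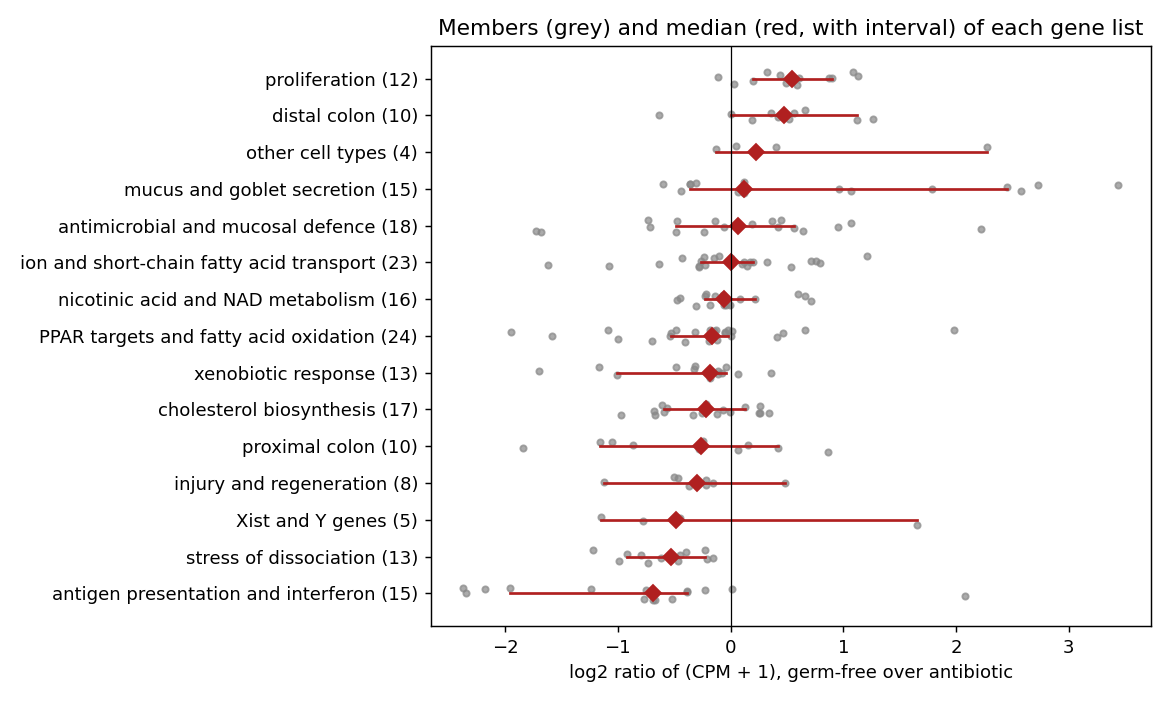
Log2 ratio of (CPM + 1), germ-free over antibiotic (horizontal), for the measured members of each gene list (grey points, 1 per gene, number of members in parentheses) and their median (red diamond, with its order-statistic interval as a red line). The lowest median is that of antigen presentation and interferon genes (-0.69) and the highest that of proliferation genes (0.54).

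Cell classes were rebuilt from fixed markers. Colonocyte-like cells were 51.9% of antibiotic cells (50.2 to 53.6) and 50.9% of germ-free cells (47.3 to 54.5). Goblet-like cells were 7.47% (6.61 to 8.40) and 11.98% (9.77 to 14.5), cycling-like cells 15.6% (14.4 to 16.9) and 27.2% (24.1 to 30.5), and stem-like cells 14.1% (12.9 to 15.3) and 1.17% (0.537 to 2.21). Unnamed cells, a cluster of low UMI counts, were 10.9% and 8.72%. The germ-free sets differed: unnamed cells were 21.2% of set 3 and 0.433% of set 4, stem-like cells 0.654% and 1.52%, and cycling-like cells 18.0% (13.8 to 22.7) and 33.3% (29.0 to 37.8), against 16.5% (14.6 to 18.5) in antibiotic cell set 3. The stem-like clusters 3 and 6 had no stem marker among their leading genes, and cluster 6 was named at a mean z-score of 0.015. The stem-like shares therefore depend on how clusters were named. The clusters of the cycling-like class went both ways. Cluster 14, led by Mki67 and Top2a, held 8.43% of antibiotic and 1.17% of germ-free cells. Cluster 8, led by Gip and Gm20528, held 0.234% and 18.1%, and its leading genes included the cycling marker Cenpf and the stem marker Slc12a2. Cluster 5, with no cycling marker among its leading genes, held 6.97% and 7.94%. The sort took proliferative and differentiated cells in equal numbers, which sets part of this balance. Some clusters, cluster 8 among them, were led by genes that differed between the conditions, so the shares were also taken from clusters made without such genes: goblet-like cells were then 7.23% and 10.5%, cycling-like cells 15.4% and 21.6%, and stem-like cells 13.9% and 4.17%. Of these cycling-like cells, the cluster led by Mki67 and Top2a held 7.09% of antibiotic and 5.86% of germ-free cells, and a cluster led by Mt2 and Sult1a1, with no cycling marker among its leading genes, 3.66% and 10.9%. The remaining cluster, also with no such marker, held 4.69% and 4.82%. These classes depended on the clustering and on the cells kept. At Leiden resolution 0.5 no cluster was stem-like, and colonocyte-like cells were 49.4% of antibiotic and 38.3% of germ-free cells. With stricter cells goblet-like cells were 10.6% and 26.6%.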

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

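The results in this part were picked because a named gene had its cell sets apart upward in one class of cells and downward in another; the differences between classes were not tested. In log2 ratio of germ-free over antibiotic, Adh1 was at 0.46 in colonocyte-like and -0.997 in cycling-like cells. B2m was at 1.18 in goblet-like and -0.66 in colonocyte-like cells, and H2-K1 at 0.45 and -0.85. Car1 was at 1.70 in cycling-like, 1.12 in goblet-like and -0.99 in colonocyte-like cells. Hoxb13 was at 1.72 in colonocyte-like and -0.86 in cycling-like cells. Itga2 was at 0.35 in colonocyte-like, 0.87 in cycling-like and -0.57 in goblet-like cells. Lypd8 was at 1.17 in goblet-like and -0.39 in colonocyte-like cells, and Muc3 at 0.94 and -0.28. The largest cluster of colonocyte-like cells was cluster 1 in the antibiotic and cluster 2 in the germ-free pool, that of cycling-like cells 14 and 8, and that of goblet-like cells 10 and 15. Germ-free cells were also shallower. Median UMI per cell were 17072 and 4840 in cluster 5, 4915.5 and 2357 in cluster 10, and 16611 and 2463.5 in cluster 15. Whether free RNA plays a part was not tested for these genes.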

How the results depend on the processing

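No paired analysis was possible because cells were not assigned to libraries and the comparison has no test. The planned count-model tests, gene set tests with preset or estimated correlation, and permutation tests were not run, since the values were deposited on a log scale with 1 pool per condition. The 24 ranked genes kept their direction under the alternatives to the contrast, though not their size. Their cell sets stayed apart except those of Cldn4 among cells with a Y-gene UMI and no Xist UMI, where 23 stayed apart. The genes had been chosen for cell sets apart. This outcome was therefore fixed in advance where 1 cell set was left out, 10 CPM was added or opposite-strand genes were removed. Adding 10 CPM shrinks the ratios of low genes by construction, to a log2 of 1.70 for Gm15592 and 4.50 for Gip. Removing genes opposite a more abundant gene takes out 6 of the 24 and leaves 18. Chosen after seeing the data were the means of per-cell values, the totals without mitochondrial genes, the removal of clusters or of opposite-strand genes, the cells with a Y-gene UMI and no Xist UMI, the z-score limit and the clustering without genes that differed 2-fold.

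The causes of the following moves were not tested. Against 111 genes higher and 118 lower, 179 were higher with stricter cells, 73 lower with 10 CPM added, 242 higher (and 137 lower) with means of per-cell values, 175 higher (and 101 lower) with totals without mitochondrial genes, 180 higher and 190 lower without the clusters of almost only germ-free cells, 186 higher among cells with a Y-gene UMI and no Xist UMI, and 63 higher without genes opposite a more abundant gene. Leaving out 1 cell set gave 94 to 478 higher and 111 to 502 lower, the highest values without germ-free cell set 4, which leaves 306 shallow cells. The median of all ranked genes moved from 0.05 to -0.05 with median-of-ratios scaling and to 0.16 with totals without mitochondrial genes. Over the alternatives the medians of lists ranged from -0.84 to -0.10 (proximal), 0.29 to 0.95 (distal), -0.17 to 0.14 (NAD), -0.49 to -0.058 (PPAR), -0.12 to 0.42 (antimicrobial), -0.13 to 0.76 (mucus), -0.57 to -0.072 (xenobiotic), -0.35 to -0.059 (cholesterol), -0.39 to 0.0021 (injury) and -0.63 to -0.23 (dissociation). The proliferation median was 0.11 after thinning and 0.10 without the germ-free clusters. The ion transport median was 0.27 with equal class shares and 0.25 without the germ-free clusters, and -0.046 to 0.21 with 1 cell set left out. The interferon list's median was -0.31 with means of per-cell values. The median of other cell types was -0.18 among cells with a Y-gene UMI and no Xist UMI.

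Single genes turned direction as follows. Areg was at 0.030 after thinning, 0.067 with equal class shares and 0.15 with per-cell means. Equal class shares gave -0.22 for Hoxb13, 0.23 for Pparg and 0.13 for Ddx3y, and per-cell means gave 0.12 for Saa1. Among cells with a Y-gene UMI and no Xist UMI, Uty was at 0.22, Eif2s3y at 0.63 and Ddx3y at 0.62. Sis was there at -0.17, and Xist at 0 by construction. Every such cell had to hold a Y-gene UMI, which weighs more in the shallower germ-free cells. The turn of these Y genes may thus come from the selection.

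Class shares are given for antibiotic and then germ-free cells. At resolution 0.5 they were 49.4% and 38.3% colonocyte-like, 7.94% and 35.2% cycling-like, 0% and 0% stem-like, and 35.1% and 14.6% unnamed. At resolution 2.0 germ-free cells were 56.6% colonocyte-like, cycling-like shares were 11.1% and 21.7%, and 15.1% of antibiotic cells were unnamed. With stricter cells germ-free cells were 37.7% colonocyte-like, cycling-like shares were 20.8% and 34.7%, goblet-like 10.6% and 26.6%, unnamed 2.74% and 0.5025%, and stem-like germ-free cells 0.5025%. With a z-score limit of 0.5 colonocyte-like shares were 38.2% and 23.8%, stem-like 8.76% and 0.521%, and unnamed 30.0% and 36.5%. Clustered without the genes that differed 2-fold, germ-free cells were 21.6% cycling-like and 4.17% stem-like. Leaving out 1 cell set gave germ-free shares of 46.7% to 53.7% colonocyte-like, 18.0% to 33.3% cycling-like and 0.433% to 21.2% unnamed. Depth limits the germ-free values: 143 germ-free and 524 antibiotic cells were too shallow to thin, and 3 counts correspond to 7.44 CPM in germ-free cell set 3.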

Other observations

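The tests of enteroendocrine cells, of the mix of cell classes and of library batches were chosen after results that bear on them had been seen, the Y-gene and Xist test was an alternative added later, and the 3 patterns, the 6 interferon genes and the limits on opposite-strand abundance were picked from the same data. Genes known from the small intestine were seen in both pools. Fabp1, a fatty acid binding protein, was at 58.3 CPM in antibiotic and 233 CPM in germ-free cells, Reg1 at 30.2 and 185 CPM, Olfm4 at 15.8 and 119 CPM, and Fabp6, an ileal bile acid binding protein, at 101 and 67.1 CPM and not apart. In germ-free cells Fabp1 was found in all clusters with at least 20 cells, between 115 and 482 CPM.

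Gip was found in germ-free cells of every cluster with at least 20 of them. A Gip UMI was in 51.2% of germ-free cells (47.6 to 54.8), where a rare type should give at most 5%, so the RNA was not confined to droplets of such a type. The share was known before the limit of 5% was set, and it cannot tell whether enteroendocrine cells alone made the RNA. An earlier test was set aside: the 5% of cells with the most Gip held 22.9% of its UMI and could hold at most 47.7%, under its limit of 50%. Free RNA in the droplets remains a candidate explanation: Gip CPM was 5.42 times as high in the 25% of cells with the fewest UMI as in the 25% with the most (4.29 to 6.84), in germ-free cell set 4. This is a hypothesis, and enteroendocrine cells or any other source of such RNA were not tested.

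A set of 6 interferon-response genes, among them Irf7, Isg15, Ifit1, Ifit3 and Oasl2, had a median log2 ratio of -2.07. A different balance of the sexes is argued against as the whole cause, since among cells with a Y-gene UMI and no Xist UMI the median was -2.00 (-3.34 to -1.04), past the limit of -1.03 (0.5 of the main value) by little at its upper end. Lower depth and another mix of cell classes stay open: the median was -1.54 after thinning (-2.56 to -1.02) and -1.38 with equal class shares (-2.11 to -0.54), past that limit but not by more than the spread of the 6 genes. Thinning also keeps each cell's expected composition, so it cannot decide on depth. The difference between library batches cannot be told apart from the condition, since 0 batches hold both conditions. A biological difference between germ-free and antibiotic-treated mice is thus a hypothesis that may hold but is not separated from batch.

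Of 195 genes whose opposite-strand gene was more than 2 times as abundant, 110 were higher and 17 lower in germ-free cells, with a median log2 ratio of 0.35 (0.26 to 0.44) against 0.05 for 4136 genes with no such partner. The median was 1.24 over the 18 whose partner was more than 16 times as abundant and 0.12 over 126 with one 1 to 2 times as abundant (39 higher, 24 lower). Lower depth stays open. The median was 0.42 after thinning (0.29 to 0.57), but thinning keeps each cell's expected composition, so it cannot decide on depth. Transcripts of the opposite-strand gene counted for the gene are a candidate explanation: across 10 clusters of germ-free cells the median Spearman rho with the partner was 0.14, above the range of matched random partners (-0.06 to 0.08), though genes that share a locus could also vary together. A difference between library batches stays open, since 0 batches hold both conditions, and no biological explanation was tested.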
